A study of Arabidopsis thaliana with 17 samples.

How the data were processed

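The series holds 17 libraries of Arabidopsis thaliana inflorescences: 6 of total RNA-seq (wild type Col-0, ddm1 and met1, 2 each), 10 of 3-prime-end RNA-seq (total RNA of the 3 genotypes and polysome-associated RNA of wild type and ddm1, 2 each) and 1 small RNA library of met1. Plants were raised in soil inside a climate chamber, RNA was extracted with TRIzol, and total RNA-seq libraries were depleted of ribosomal RNA, per the labels. Per the submitters' processing notes, reads were trimmed with Trimmomatic, aligned to TAIR10 with STAR and counted with edgeR, with no versions or settings given. The treatment of reads that align to several places, the use of strand in counting and the annotation behind the features are not stated.

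The deposited tables of both assays hold CPM, reads of a feature per 1000000 counted reads of the library, scaled by the authors. Within 0.001 reads, 100% of values above 0 were whole multiples of the smallest in their column, taken as 1 read. Columns summed to 1000000, so no further scaling factor was used. The deposited small RNA file holds counts, the number of reads of each distinct sequence, without positions in the genome. Each table has 60888 features: 29699 genes, of which 28932 were matched to the reference for their names, and 31189 transposon annotations, for which the tables and the reference give neither names nor families. The reference is of another assembly release than the notes name, so it gave gene names only. EVD, CAC1 and VANDAL21 are names assigned from general knowledge of their annotation identifiers, and 3 of the 20 listed identifiers of such elements passed the filter.

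Total RNA-seq libraries held 52324341 to 69728246 counted reads, so that 1 read is at most 0.0191 CPM. The 3-prime-end libraries held 3436653 to 10664952, so that 1 read is at most 0.291 CPM. Median absolute log2 differences between replicates were 0.0887 to 0.0945 in total RNA-seq and 0.271 to 0.476 in 3-prime-end RNA. Chi-square statistics per degree of freedom between replicates ran from 7.83 to 53.9, above what counting alone gives, so intervals for counting error were not used to compare groups. Nothing in the labels says that replicates came from separate plants, so the p-values measure only the spread between these samples. With 2 libraries against 2, an exact permutation test cannot give a two-sided p below 0.333, so moderated tests that share spread between features were used.

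Before the data were examined, the groups, comparisons, tests, gene lists, alternatives and the rule for named genes were fixed. Features with at least 1 CPM in at least 2 libraries of a table were tested with limma-trend on log2 of CPM plus 0.5, with all groups of the table in the fit, and called at a Benjamini-Hochberg adjusted p under 0.05. The 9 comparisons were ddm1 and met1 with wild type and met1 with ddm1 in total RNA-seq, ddm1 and met1 with wild type in 3-prime-end total RNA, polysome with total RNA in wild type and in ddm1, ddm1 with wild type on polysomes, and the interaction of genotype and fraction. The comparisons of ddm1 and met1 with wild type share their control libraries. No test was made across the 2 assays. A fold against a group without a read was computed against a floor of 3 reads per library.

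The 14 gene lists, written from general knowledge, were silencing machinery, methylation-controlled genes, named LTR and DNA elements, floral organ and meristem regulators, pollen markers, tapetum markers, photosynthesis, biotic and abiotic stress, DNA damage response, cytosolic ribosomal proteins, translation factors, replication-type histones, conserved upstream ORF genes, and noncoding TAS and phosphate-starvation RNAs. Lists with at least 5 tested members and the transposon annotations were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with estimated correlation and with fry. Transposon annotations that rose in ddm1 3-prime-end total RNA were tested in the same way against all genes for the polysome comparison of ddm1, and 10000 lists of genes matched in level over 10 bins were drawn after the result was seen. The heat-shock list, 18 tested genes with a heat-shock symbol in the reference, was also made after the data were seen. Small RNA shares have exact binomial 95% limits.

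Named features were MET1 and DDM1, and, for 5 main comparisons, the 6 genes with the largest positive and the 6 with the largest negative log2 difference among those called, with no overlap between the libraries and a mean of at least 5 CPM in the higher group, the 6 transposon annotations with the largest absolute difference, and up to 4 called members per gene list, or the largest where none was called. The other comparisons named 3 of each kind. The report gives some of these, and the heat-shock gene HSP1 was picked after its values were seen. Where leaving out a library ended the call of a named feature, the highest adjusted p found is given after the words up to.

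The alternatives were pseudocounts of 0.1 and 1, no filter and a filter of 5 CPM, median-of-ratios scaling, quantile normalization, a fit with only the compared groups, no trend of the variance, a fold of at least 2, edgeR quasi-likelihood tests and DESeq2 on the recovered reads, replicate number as a block, and leaving out each library in turn. Nuclear features only, calls also made in total RNA-seq, and elements chosen in total RNA-seq were added after the data were seen. Replicate numbers did not pair the libraries: correlations of residuals between equal numbers ran from -0.187 to 0.129 in 3 pairs of groups of total RNA-seq and from -0.124 to 0.0654 in 10 of 3-prime-end RNA. A test of Copia elements against other classes, family means and small RNA positions were planned and left out, as the files lack classes, families and positions.

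Tests were run on simulated data in each table's layout, with 200 changed features and a shifted list of 30. The shares found need not hold in real data. In a total RNA-seq comparison limma recovered 100% of 2-fold changes. In 3-prime-end total RNA it recovered 5.97% of 2-fold, 71.6% of 4-fold and 90.9% of 8-fold changes, and for the interaction 0%, 28.4% and 69.7%. The shares of false calls were 9.80% for total RNA-seq, 12.0% for 3-prime-end total RNA, 8.15% for polysome against total RNA and 9.72% for the interaction, above the nominal 5%. They were 7.46% to 10.7% for edgeR and 15.7% to 20.1% for DESeq2. Tools were R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.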

Results

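RNA was measured in inflorescences of Arabidopsis thaliana plants of 3 genotypes, wild type of the Col-0 accession, ddm1 and met1. The ddm1 mutant lacks a chromatin remodeller needed to keep DNA methylated in silent chromatin. The met1 mutant lacks the main methyltransferase that maintains CG methylation. Total RNA-seq, made from RNA depleted of ribosomal RNA, covered each genotype with 2 libraries, 6 in all. A second assay read the 3-prime ends of polyadenylated RNA in 10 libraries, 2 per group. They covered total RNA of the 3 genotypes, and polysome-associated RNA, the RNA bound by several ribosomes, of wild type and ddm1. A single small RNA library of met1 held 82331892 reads. Each table counted 60888 features, of which 29420 were nuclear genes, 133 chloroplast genes, 146 mitochondrial genes and 31189 transposon annotations. Levels are given in CPM as mean ± SD of 2 libraries, and differences as log2 differences ± SE of limma, with its Benjamini-Hochberg adjusted p. Tests were made only within an assay.

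Reads in transposon annotations made up 0.453% and 0.399% of the wild-type total RNA-seq libraries, 7.67% and 7.53% of those of ddm1 and 5.49% and 5.38% of those of met1. In 3-prime-end libraries of total RNA the shares were 0.639% and 0.710% in wild type, 6.17% and 5.85% in ddm1 and 3.50% and 3.94% in met1. Polysome-associated RNA held 0.634% and 0.738% in wild type and 2.17% and 2.04% in ddm1. In each comparison of a mutant with wild type the groups' shares lay further apart than replicates did.

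**Figure D1:**
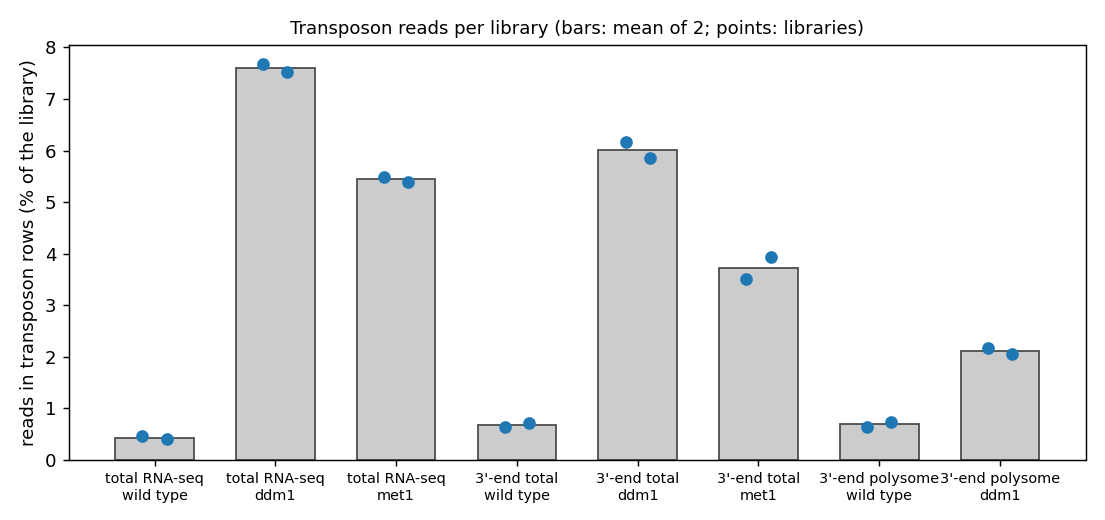
Reads in transposon annotations as a percentage of all counted reads (vertical axis) for each group (horizontal axis), with bars at the mean of 2 libraries and points for single libraries. The ddm1 polysome libraries lie at 2.17% and 2.04%, between the wild-type polysome libraries and the ddm1 total RNA libraries at 6.17% and 5.85%.

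The first comparison asked which RNAs change when DDM1 is lost, in total RNA-seq. DDM1 RNA itself (AT5G66750, listed as CHR1 in the reference) was lower in ddm1. It stood at 7.62 ± 0.0878 CPM against 20.8 ± 1.38 CPM in wild type (log2 -1.39 ± 0.11, adjusted p = 1.18e-05). MET1 RNA (AT5G49160) was higher, at 64.4 ± 3.02 CPM against 44.3 ± 0.560 CPM (log2 0.53 ± 0.06, adjusted p = 0.000145). Of 2144 transposon annotations tested, 1690 rose and 208 fell (108 after median-of-ratios scaling), with a median log2 difference of 2.95 (4.77 with groups without a read set to 3 reads per library). Camera placed them above the other features (adjusted p = 6.26e-132, and 0.00438 with an estimated correlation between genes, marked estimated below). Over all 22500 features tested, 15570 were called, 3185 higher and 12385 lower, and 4378 of them differed at least 2-fold. The split depended on the scaling: CPM put the median of all features at log2 -0.28, and median-of-ratios scaling (rescaling below, with list counts over all features), which put it at 0.02, gave 11983 calls, 6548 higher and 5435 lower.

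The transposon annotations with the largest differences were near 0 CPM in wild type. They included AT5TE42470 (1899.7 ± 223 CPM against 0.250 ± 0.154 CPM, log2 11.32 ± 0.13, adjusted p = 9.80e-11), AT5TE42710 (log2 11.15 ± 0.05, adjusted p = 5.16e-12) and AT3TE67635 (log2 11.14 ± 0.16, adjusted p = 3.18e-10). The annotations taken to be CAC1, a CACTA DNA transposon, EVD, a Ty1/Copia retrotransposon, and VANDAL21, a Mutator-like DNA transposon, all rose, 3 of the 3 listed elements tested. CAC1 (AT2TE20205) stood at 1355 ± 148 CPM in ddm1 (log2 10.98 ± 0.13, adjusted p = 9.88e-11), EVD (AT5TE20395) at 184 ± 0.538 CPM (log2 8.26 ± 0.12, adjusted p = 3.29e-10) and VANDAL21 (AT2TE42810) at 86.9 ± 8.79 CPM (log2 7.22 ± 0.10, adjusted p = 2.96e-10). Adjusted over the list alone 3 of 3 passed, but they met the filter in mutants only. The counting of reads shared by near-identical copies is not stated, so values of single transposon annotations are uncertain.

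Among genes, the largest rises were those of AT1G59930 (281 ± 41.2 CPM against 0.0215 ± 0.0304 CPM, log2 9.07 ± 0.10, adjusted p = 6.40e-11) and AT1G59920 (log2 8.61 ± 0.12, adjusted p = 2.25e-10). The largest falls were those of DAF1 (AT3G62230, 0.578 ± 0.129 CPM against 76.3 ± 2.61 CPM, log2 -6.16 ± 0.10, adjusted p = 7.72e-10) and AT4G21895 (log2 -5.12 ± 0.12, adjusted p = 7.38e-09). Of the 10 tested genes known to be controlled by DNA methylation, 5 rose and 3 fell (5 and 3 adjusted over the list alone, 6 and 2 after rescaling). Camera placed this list above other features (adjusted p = 0.0228, but 0.471 estimated and 0.138 after rescaling). FWA (AT4G25530, a homeobox gene silenced by promoter methylation, 61.7 ± 17.5 CPM against 0.724 ± 0.273 CPM, log2 5.66 ± 0.20, adjusted p = 7.80e-08), SDC (AT2G17690, an F-box gene silenced by methylated repeats, log2 5.58 ± 0.11, adjusted p = 2.04e-09) and QQS (AT3G30720, log2 3.72 ± 0.28, adjusted p = 1.10e-05) rose, and BNS (AT1G73177, log2 -2.10 ± 0.19, adjusted p = 2.94e-05) fell. Of all 20356 genes, 1495 rose and 12177 fell (4821 and 5327 after rescaling), a background for all lists. Of the 35 silencing genes, 4 rose and 21 fell (4 and 21 adjusted over the list alone, 10 and 15 after rescaling). Silencing genes did not pass camera (adjusted p = 0.264). Those that fell included the Argonaute genes AGO9 (AT5G21150, log2 -1.71 ± 0.10, adjusted p = 2.15e-06) and AGO5 (AT2G27880, log2 -1.64 ± 0.12, adjusted p = 9.27e-06), in libraries where pollen and tapetum markers fell too.

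Floral and anther genes were mostly lower in ddm1. Of the 6 pollen markers tested, 0 rose and 6 fell (0 and 6 adjusted over the list alone). Camera placed pollen markers below other features (adjusted p = 0.00193, but 0.445 estimated). VGD1 (AT2G47040, a pollen tube pectin methylesterase, 50.7 ± 3.40 CPM against 588 ± 24.7 CPM, log2 -3.52 ± 0.10, adjusted p = 1.61e-08) and BCP1 (AT1G24520, log2 -3.67 ± 0.09, adjusted p = 9.34e-09) were among them. All 10 tapetum markers tested, genes of the nutritive layer around the pollen, fell (10 adjusted over the list alone), for example GRP17 (AT5G07530, a pollen coat protein, log2 -3.07 ± 0.20, adjusted p = 5.38e-06) and LAP6 (AT1G02050, log2 -1.96 ± 0.31, adjusted p = 7.61e-04). Camera placed tapetum markers below other features (adjusted p = 0.0350, but 0.642 estimated). Of the 19 floral organ and meristem regulators, measured in libraries that also differed in these markers, 1 rose and 15 fell (1 and 15 adjusted over the list alone, 3 and 11 after rescaling). Camera placed this list below other features (adjusted p = 0.0350, but 0.471 estimated). FT (AT1G65480, the mobile flowering signal, log2 -2.18 ± 0.22, adjusted p = 7.20e-05) and WUS (AT2G17950, a stem cell regulator, log2 -1.67 ± 0.16, adjusted p = 4.87e-05) fell.

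Of the 13 photosynthesis genes, 9 rose and 1 fell (9 and 1 adjusted over the list alone, 11 and 0 after rescaling). Camera placed photosynthesis genes above other features (adjusted p = 6.43e-07, but 0.445 estimated). The antenna protein genes LHCB1.1 (AT1G29920, 1332 ± 41.6 CPM against 138 ± 19.9 CPM, log2 3.27 ± 0.10, adjusted p = 3.53e-08) and LHCB2.1 (AT2G05100, log2 2.83 ± 0.08, adjusted p = 1.73e-08) rose most, although reads of LHCB1 copies are hard to tell apart. Of the 9 DNA damage response genes tested, 6 rose and 1 fell (6 and 1 adjusted over the list alone, 7 and 0 after rescaling). Camera placed DNA damage genes above other features (adjusted p = 0.00287, but 0.602 estimated). PARP2 (AT4G02390, a poly(ADP-ribose) polymerase, log2 0.85 ± 0.10, adjusted p = 1.14e-04) and TSO2 (AT3G27060, a ribonucleotide reductase subunit, log2 0.79 ± 0.09, adjusted p = 1.31e-04) rose. Of the 11 biotic and abiotic stress genes tested, 4 rose and 4 fell (4 and 4 adjusted over the list alone, 5 and 2 after rescaling). Stress genes did not pass camera (adjusted p = 0.227, upward of the others, with median log2 0.05 and mean log2 -0.01). The pathogenesis-related gene PR2 (AT3G57260, log2 1.67 ± 0.29, adjusted p = 0.00130) rose and the cold-induced gene KIN1 (AT5G15960, log2 -1.98 ± 0.14, adjusted p = 8.40e-06) fell. Of the 20 genes with a conserved upstream open reading frame, a short leader reading frame that represses translation, 0 rose and 12 fell (0 and 12 adjusted over the list alone, 2 and 7 after rescaling). This list did not pass camera (adjusted p = 0.155). SAMDC3 (AT3G25570, log2 -1.61 ± 0.12, adjusted p = 9.54e-06) and PAO4 (AT1G65840, a polyamine oxidase, log2 -1.13 ± 0.07, adjusted p = 4.77e-06) fell.

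How many genes of the protein synthesis apparatus were called depended on the scaling, and the cause was not tested. Of the 18 cytosolic ribosomal protein genes, 6 rose and 0 fell (0 and 0 adjusted over the list alone, 18 and 0 after rescaling). Camera placed ribosomal protein genes above other features (adjusted p = 2.97e-04, but 0.616 estimated). The largest difference was that of RPS6A (AT4G31700, log2 0.31 ± 0.08, adjusted p = 0.00894, up to 0.0583 without wild type replicate 1 or ddm1 replicate 1). Of the 9 translation factor genes, 0 rose and 1 fell (0 and 0 adjusted over the list alone, 6 and 0 after rescaling). Translation factor genes did not pass camera (adjusted p = 0.350, upward of the others, with median log2 -0.01 and mean log2 -0.06). The 1 that fell was EF1A-A3 (AT1G07920, log2 -0.32 ± 0.10, adjusted p = 0.0244, up to 0.115 without wild type replicate 2 or ddm1 replicate 1), which has near-identical copies and whose log2 difference was -0.00346 under median-of-ratios scaling. Of the 13 replication-type histone genes, labelled here H3.1a to H3.1e and H4a to H4h, 5 rose and 1 fell (5 and 1 adjusted over the list alone, 10 and 0 after rescaling). Camera placed histone genes above other features (adjusted p = 0.0180, but 0.642 estimated), with reads of identical copies hard to tell apart. H3.1a (AT5G65360, log2 0.30 ± 0.07, adjusted p = 0.00442) had the largest difference, and H4a (AT1G07660, log2 -0.27 ± 0.07, adjusted p = 0.0104, up to 0.0640 without ddm1 replicate 2), at log2 0.04 after rescaling, was the member that fell. Of the 6 noncoding trans-acting siRNA precursors and phosphate-starvation RNAs tested, 0 rose and 2 fell (0 and 1 adjusted over the list alone, 0 and 0 after rescaling), and these noncoding RNAs did not pass camera (adjusted p = 0.867, upward of the others, with median log2 -0.18 and mean log2 -0.16). TAS1B (AT1G50055, log2 -0.55 ± 0.11, adjusted p = 0.00339, but adjusted p = 0.0737 under median-of-ratios scaling) and TAS2 (AT2G39681, log2 -0.34 ± 0.11, adjusted p = 0.0284, up to 0.176 without wild type replicate 1 or ddm1 replicate 2) were lower.

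The same question was asked of MET1. MET1 RNA in met1 was 36.0 ± 1.66 CPM against 44.3 ± 0.560 CPM in wild type (log2 -0.30 ± 0.06, adjusted p = 0.00548), and edgeR and DESeq2 did not call it (adjusted p = 0.0575 and 0.105). The labels do not say which part of the gene the mutation affects. DDM1 RNA was higher, at 31.2 ± 4.71 CPM against 20.8 ± 1.38 CPM (log2 0.57 ± 0.11, adjusted p = 0.00336). FWA rose to 459 ± 17.9 CPM from 0.724 ± 0.273 CPM (log2 8.57 ± 0.20, adjusted p = 7.78e-09) and SDC to 157 ± 17.58 CPM from 0.380 ± 0.111 CPM (log2 7.48 ± 0.11, adjusted p = 3.96e-10). ROS1 (AT2G36490), a DNA demethylase gene, fell to 5.05 ± 0.331 CPM from 166 ± 1.05 CPM (log2 -4.91 ± 0.08, adjusted p = 6.08e-10). Of 2144 transposon annotations tested, 1542 rose and 146 fell, with a median log2 difference of 2.11 (3.18 at the 3-read floor), and with quantile normalization 1225 rose and 348 fell, with a median of 1.23. Camera placed them above the other features (adjusted p = 4.69e-97, and 0.00698 estimated). Over all features 10539 were called, 3079 higher and 7460 lower, 2732 of them by at least 2-fold. With median-of-ratios scaling, which moved the median of all features from log2 -0.13 to 0.01, 9149 were called, 4791 higher and 4358 lower, and without wild-type replicate 1 the count was 6845.

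The largest transposon differences were those of AT5TE42470 (2021 ± 6.72 CPM against 0.250 ± 0.154 CPM, log2 11.41 ± 0.13, adjusted p = 1.08e-10) and AT5TE42710 (log2 11.17 ± 0.05, adjusted p = 5.76e-12). All 3 listed elements tested rose, in the count adjusted over the list alone too: EVD reached 11.04 ± 2.06 CPM (log2 4.25 ± 0.12, adjusted p = 2.92e-08), CAC1 71.7 ± 11.5 CPM (log2 6.74 ± 0.13, adjusted p = 2.42e-09) and VANDAL21 76.2 ± 6.52 CPM (log2 7.04 ± 0.10, adjusted p = 4.17e-10). Of the 10 methylation-controlled genes tested, 6 rose and 2 fell (6 and 2 adjusted over the list alone). Camera placed this list above other features (adjusted p = 0.0272, but 0.464 estimated and 0.127 after rescaling). Of the 35 silencing genes, measured where pollen markers fell too, 4 rose and 10 fell (4 and 10 adjusted over the list alone, 10 and 7 after rescaling). Silencing genes did not pass camera (adjusted p = 0.693). IBM1 (AT3G07610, a histone demethylase gene, log2 -1.19 ± 0.06, adjusted p = 1.45e-06) fell besides ROS1. Other genes with large differences were AT1G59930 (log2 9.41 ± 0.10, adjusted p = 5.89e-11), which rose, and AT1G25141 (log2 -4.20 ± 0.24, adjusted p = 3.60e-06) and the transcribed pseudogene AT1G24792 (log2 -4.07 ± 0.21, adjusted p = 1.66e-06), which fell and for which reads of near-identical copies are uncertain.

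Of the 6 pollen markers tested, all fell (6 adjusted over the list alone), for example VGD1 (log2 -1.07 ± 0.10, adjusted p = 5.52e-05). Camera placed pollen markers below other features (adjusted p = 0.00810, but 0.464 estimated). Of the 10 tapetum markers, 0 rose and 1 fell (0 and 1 adjusted over the list alone), GRP17 (log2 -1.12 ± 0.20, adjusted p = 0.00299). Tapetum markers did not pass camera (adjusted p = 0.693, upward of the others, with median log2 -0.08 and mean log2 -0.10). The met1 libraries stood apart on such markers, with A6 at 127 and 55.2 CPM against 77.3 and 96.9 CPM in wild type, LAP6 at 67.8 and 32.2 against 42.9 and 59.9 CPM, LAP5 at 74.2 and 38.5 against 37.4 and 55.6 CPM, and CYP703A2 at 42.1 and 18.6 against 21.8 and 25.5 CPM. Of the 19 floral and meristem regulators, beside these pollen markers, 1 rose and 10 fell (1 and 11 adjusted over the list alone, 3 and 9 after rescaling). This list did not pass camera (adjusted p = 0.0716). FT (log2 -2.14 ± 0.22, adjusted p = 1.47e-04) and SEP2 (AT3G02310, a floral organ identity gene, log2 -1.87 ± 0.11, adjusted p = 3.27e-06) fell. Of the 13 photosynthesis genes, 9 rose and 1 fell (9 and 1 adjusted over the list alone, 10 and 1 after rescaling). Camera placed photosynthesis genes above other features (adjusted p = 7.69e-05, but 0.464 estimated). Of the 9 DNA damage response genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone, 8 and 0 after rescaling). Camera placed DNA damage genes above other features (adjusted p = 0.00202, but 0.464 estimated). Of the 11 stress genes, 5 rose and 2 fell (6 and 2 adjusted over the list alone, 7 and 2 after rescaling). Camera placed stress genes above other features (adjusted p = 0.0230, but 0.464 estimated and 0.0652 after rescaling). LHCB1.1 (log2 2.25 ± 0.10, adjusted p = 6.18e-07), TSO2 (log2 0.72 ± 0.09, adjusted p = 3.87e-04) and PR2 (log2 3.12 ± 0.29, adjusted p = 7.06e-05) rose.

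Of the 18 ribosomal protein genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone, 11 and 0 after rescaling). Camera placed ribosomal protein genes above other features (adjusted p = 0.0156, but 0.642 estimated). Limma called 0 of these genes (2 at an unadjusted p, 11 by edgeR and 14 by DESeq2, and 0 adjusted over the list alone) and 0 of the 9 translation factor genes (0 at an unadjusted p, 3 by edgeR and 6 by DESeq2, and 0 adjusted over the list alone). Of the 13 histone genes, 5 rose and 0 fell (5 and 0 adjusted over the list alone, 8 and 0 after rescaling). Camera placed histone genes above other features (adjusted p = 0.0230, but 0.642 estimated). H3.1a (log2 0.39 ± 0.07, adjusted p = 0.00205) was the histone gene with the largest difference. Of the 20 genes with a conserved upstream open reading frame, 1 rose and 5 fell (1 and 5 adjusted over the list alone, 3 and 4 after rescaling). This list did not pass camera (adjusted p = 0.513). Of the 6 noncoding RNAs tested, 0 rose and 3 fell (0 and 3 adjusted over the list alone, 0 and 1 after rescaling), with TAS1B (log2 -0.77 ± 0.11, adjusted p = 0.00109) among them, and these noncoding RNAs did not pass camera (adjusted p = 0.292).

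Comparing met1 with ddm1 asked where they differ, with wild type entering only the filter and spread. MET1 RNA was lower in met1 (log2 -0.83 ± 0.06, adjusted p = 3.69e-05) and DDM1 RNA lower in ddm1 (log2 1.96 ± 0.11, adjusted p = 5.99e-06, met1 minus ddm1). Of 2144 transposon annotations tested, 983 were lower (542 and 575 without ddm1 replicate 1 or 2) and 290 higher in met1 (123, 176 and 190 without met1 replicate 1, met1 replicate 2 or ddm1 replicate 2, and 183 after rescaling), with a median log2 difference of -0.29. Camera placed them below the other features (adjusted p = 1.10e-38, and 0.0279 estimated). AT3TE16035 (0.238 ± 0.0349 CPM against 128 ± 14.6 CPM, log2 -7.44 ± 0.12, adjusted p = 9.57e-08) and AT1TE45315 (log2 -7.39 ± 0.12, adjusted p = 9.57e-08) had the largest differences. Of the listed elements, 0 were higher and 2 were lower in met1 (0 and 2 adjusted over the list alone, 0 and 3 after rescaling), and VANDAL21 was not called. All 6 pollen and 10 tapetum markers tested were higher in met1 (6 and 10 adjusted over the list alone, medians of log2 2.38 and 1.81), and camera placed both lists above the other features (adjusted p = 2.37e-05 and 0.00114, but 0.324 and 0.772 estimated). Of the 13 photosynthesis genes, 0 were higher and 7 were lower in met1 (0 and 7 adjusted over the list alone, 0 and 9 after rescaling). Camera placed photosynthesis genes below other features (adjusted p = 2.37e-05, but 0.599 estimated). Among single genes, AT1G58602 (log2 3.23 ± 0.08, adjusted p = 2.53e-07) was higher in met1, and AT3G60950 (0.504 ± 0.203 CPM against 61.2 ± 5.02 CPM, log2 -5.95 ± 0.17, adjusted p = 3.61e-07) and AT3G61030 (log2 -5.75 ± 0.13, adjusted p = 1.47e-07) were lower. Over all features 9110 were called, 6997 higher and 2113 lower, 1971 of them by at least 2-fold. Median-of-ratios scaling, which moved the median of all features from log2 0.15 to -0.01, gave 6748 calls, 2940 higher and 3808 lower, and leaving out ddm1 replicate 1, ddm1 replicate 2 or met1 replicate 1 gave 5269, 5709 and 4852 calls.

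The ddm1 mutant was compared with wild type again in 3-prime-end total RNA, the baseline for the polysome data. DDM1 RNA was 1.11 ± 0.461 CPM in ddm1 against 6.66 ± 2.35 CPM (log2 -2.14 ± 0.76, adjusted p = 0.0845, so not called), and MET1 RNA was 28.9 ± 0.875 CPM against 30.4 ± 0.556 CPM (log2 -0.07 ± 0.30, adjusted p = 0.917). Of 1983 transposon annotations tested, 1089 rose and 59 fell, with a median log2 difference of 2.40 (2.49 at the 3-read floor). Camera placed them above the other features (adjusted p = 1.79e-60, and 7.05e-04 estimated). AT5TE42470 rose to 2880.3 ± 162 CPM from 0.701 ± 0.150 CPM (log2 11.23 ± 0.38, adjusted p = 7.14e-10), EVD rose to 102 ± 33.8 CPM from 1.21 ± 1.71 CPM (log2 6.37 ± 0.77, adjusted p = 8.62e-05), and VANDAL21, with no wild-type read, rose at least 337-fold (adjusted p = 2.34e-09), to 142 ± 1.16 CPM. CAC1, at 0.471 ± 0.666 CPM in ddm1 and without a read in wild type, was not called, which left 2 of 3 listed elements called, also when adjusted over the list alone. Over all 22134 features tested, 3206 were called, 1592 higher and 1614 lower. Median-of-ratios scaling moved the median of all features from log2 -0.08 to 0.04, and the count without wild-type replicate 1, wild-type replicate 2 or ddm1 replicate 2 was 2038, 1937 and 2050.

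The largest falls among genes were those of heat-shock genes, which were high in wild type. HSP17.6A (AT5G12030), a small heat-shock protein, stood at 1.46 ± 0.374 CPM in ddm1 against 712 ± 35.4 CPM (log2 -8.52 ± 0.61, adjusted p = 5.95e-07), and HSFA2 (AT2G26150), a heat-stress transcription factor, at 4.66 ± 1.84 CPM against 1313 ± 6.80 CPM (log2 -8.04 ± 0.51, adjusted p = 2.12e-07). AT1G59860 (log2 -8.79 ± 0.56, adjusted p = 1.87e-07) and HSP17.4 (AT3G46230, log2 -8.38 ± 0.80, adjusted p = 9.40e-06) fell as well. Of 18 tested genes with a heat-shock symbol in the reference, a list made after the values were seen, 12 were lower in ddm1 and 1, HSP1 (AT4G14830, log2 1.38, adjusted p = 0.0394), was higher. Their median level was 195 and 206 CPM in the wild-type libraries, 12.5 and 10.9 CPM in those of ddm1 and 15.9 and 11.8 CPM in those of met1. Of the 13 biotic and abiotic stress genes tested, among them heat-shock genes, 0 rose and 6 fell (0 and 7 adjusted over the list alone). Camera placed stress genes below other features (adjusted p = 1.38e-04, but 0.205 estimated). HSP101 (AT1G74310, log2 -7.25 ± 0.63, adjusted p = 4.02e-06) and HSP90.1 (AT5G52640, log2 -6.95 ± 0.50, adjusted p = 6.74e-07), both chaperones, were among them.

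**Figure D2:**
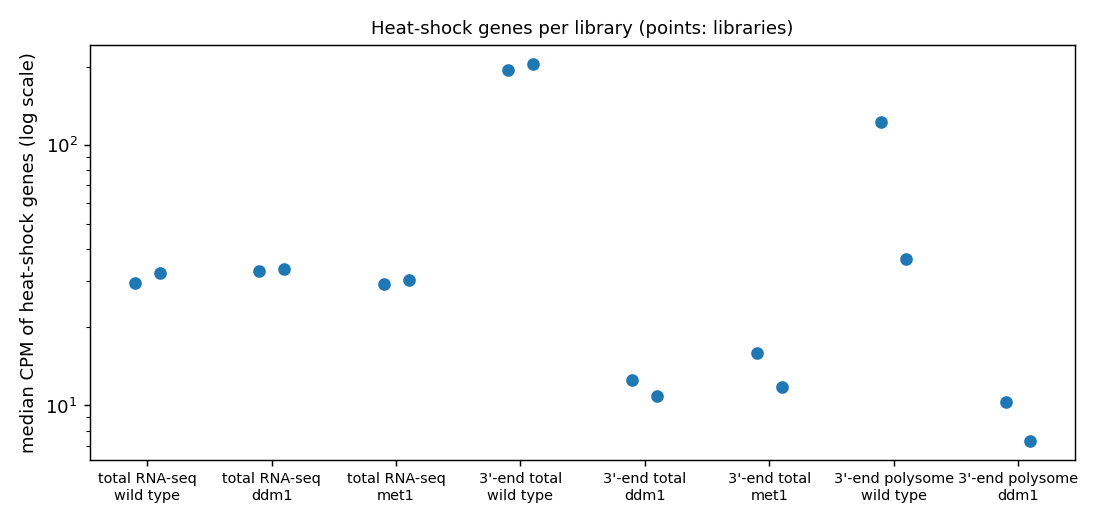
Median level of heat-shock genes in CPM (vertical axis, log scale) in each library (points) of each group (horizontal axis). The wild-type 3-prime-end libraries of total RNA lie at 195 and 206 CPM, above those of both mutants.

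The largest rises among genes included AT5G26270 (1199 ± 150.4 CPM against 0.1996 ± 0.0541 CPM, log2 10.74 ± 0.27, adjusted p = 8.76e-11), AT3G25720 (log2 9.79 ± 0.30, adjusted p = 2.98e-10) and OFP9 (AT4G04030), which had no wild-type read and rose at least 664-fold (adjusted p = 3.27e-10), to 279 ± 25.5 CPM. Of the 9 methylation-controlled genes tested, 4 rose and 1 fell (4 and 2 adjusted over the list alone). This list did not pass camera (adjusted p = 0.0991). SDC (log2 5.38 ± 0.52, adjusted p = 1.19e-05), QQS (log2 4.40 ± 0.34, adjusted p = 1.16e-06) and HISN6B (AT1G71920, log2 4.20 ± 0.73, adjusted p = 0.00158) rose, and ROS1 fell to 0.875 ± 0.794 CPM from 31.5 ± 8.59 CPM (log2 -4.65 ± 0.60, adjusted p = 1.52e-04). Of the 35 silencing genes, measured where pollen and tapetum markers fell too, 0 rose and 5 fell (0 and 5 adjusted over the list alone), AGO5 (log2 -2.53 ± 0.36, adjusted p = 3.01e-04) among them. Camera placed silencing genes below other features (adjusted p = 0.00741, but 0.205 estimated). All 6 pollen markers tested fell (6 adjusted over the list alone), for example BCP1 (log2 -3.70 ± 0.43, adjusted p = 5.79e-05). Camera placed pollen markers below other features (adjusted p = 3.26e-06, but 0.205 estimated). Of the 9 tapetum markers tested, 0 rose and 6 fell (0 and 7 adjusted over the list alone), ATA7 (AT4G28395, log2 -1.69 ± 0.32, adjusted p = 0.00281) among them. Camera placed tapetum markers below other features (adjusted p = 1.30e-04, but 0.205 estimated). Of the 19 floral and meristem regulators, beside these anther markers, 0 rose and 4 fell (0 and 5 adjusted over the list alone), WUS (log2 -2.07 ± 0.29, adjusted p = 3.26e-04) among them. Camera placed this list below other features (adjusted p = 0.0136, but 0.475 estimated). Of the 13 photosynthesis genes, 5 rose and 0 fell (10 and 0 adjusted over the list alone), RBCS1A (AT1G67090, a Rubisco small subunit gene, log2 1.11 ± 0.19, adjusted p = 0.00140) among them. Camera placed photosynthesis genes above other features (adjusted p = 7.85e-06, but 0.205 estimated).

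In the same comparison, of the 20 genes with a conserved upstream open reading frame 0 rose and 3 fell (0 and 3 adjusted over the list alone), with BZIP53 (AT3G62420, log2 -1.14 ± 0.19, adjusted p = 0.00101). This list did not pass camera (adjusted p = 0.107). Of the 6 noncoding RNAs tested, 1 rose and 0 fell (1 and 0 adjusted over the list alone), namely TAS3A (AT3G17185, a trans-acting siRNA precursor, log2 1.84 ± 0.25, adjusted p = 2.71e-04), and these noncoding RNAs did not pass camera (adjusted p = 0.0991). Limma called 0 of the 9 DNA damage genes (1 at an unadjusted p, 0 by edgeR and 0 by DESeq2, and 0 adjusted over the list alone), 0 of the 18 ribosomal protein genes (1 at an unadjusted p, 0 by edgeR and 1 by DESeq2, and 0 adjusted over the list alone), 0 of the 9 translation factor genes (0 at an unadjusted p, 0 by edgeR and 0 by DESeq2, and 0 adjusted over the list alone) and 0 of the 13 histone genes (4 at an unadjusted p, 1 by edgeR and 2 by DESeq2, and 0 adjusted over the list alone). None of these 4 lists passed camera (adjusted p = 0.585, 0.133, 0.566 and 0.0991).

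In 3-prime-end total RNA, met1 was also compared with wild type. MET1 RNA was 17.7 ± 2.77 CPM in met1 against 30.4 ± 0.556 CPM (log2 -0.78 ± 0.30, adjusted p = 0.152), and DDM1 RNA 7.52 ± 8.30 CPM against 6.66 ± 2.35 CPM (log2 -0.35 ± 0.76, adjusted p = 0.857), neither of them called. FWA rose to 417 ± 85.8 CPM from 1.45 ± 1.38 CPM (log2 7.94 ± 0.69, adjusted p = 5.47e-06). Of the transposon annotations, 770 rose and 29 fell, with a median log2 difference of 1.38 (1.39 at the 3-read floor). Camera placed them above the other features (adjusted p = 2.33e-35, and 0.00264 estimated). AT5TE42470 (log2 10.55 ± 0.38, adjusted p = 1.79e-09) had the largest difference, and of the listed elements 2 rose and 0 fell (2 and 0 adjusted over the list alone). HSP17.6A (log2 -9.94 ± 0.61, adjusted p = 1.83e-07) fell, 12 of the 18 heat-shock genes were lower than in wild type, and HSP1 was higher (log2 1.48, adjusted p = 0.0418). With median-of-ratios scaling HSP1 was not called in met1 (adjusted p = 0.0529), the cause was not tested, and HSP1 was not tested with libraries left out. Of the 13 stress genes, 0 rose and 7 fell (1 and 7 adjusted over the list alone). Camera placed stress genes below other features (adjusted p = 2.15e-07, but 0.241 estimated). Of the 9 methylation-controlled genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone). Camera placed this list above other features (adjusted p = 0.0343, but 0.241 estimated). Of the 19 floral and meristem regulators 0 rose and 4 fell (0 and 4 adjusted over the list alone). Camera placed this list below other features (adjusted p = 0.00315, but 0.485 estimated). Of the 35 silencing genes 0 rose and 2 fell (0 and 2 adjusted over the list alone), and of the 13 photosynthesis genes 3 rose and 0 fell (5 and 0 adjusted over the list alone). Limma called 0 of the 6 pollen markers (2 at an unadjusted p, 0 by edgeR and 0 by DESeq2, and 1 adjusted over the list alone), 0 of the 9 tapetum markers (1 at an unadjusted p, 0 by edgeR and 0 by DESeq2, and 0 adjusted over the list alone) and 0 of the 9 DNA damage genes (0 at an unadjusted p, 0 by edgeR and 0 by DESeq2, and 0 adjusted over the list alone, median log2 -0.27). Camera placed pollen markers below other features (adjusted p = 0.0343, but 0.485 estimated). Over all features 1969 were called, 1346 higher and 623 lower, against 1110 and 793 with quantile normalization, which moved the median of all features from log2 0.08 to -0.08. In the same direction, 1052 of these features were also called in total RNA-seq, and without wild-type replicate 1 or wild-type replicate 2 the count was 1214 and 1254.

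Polysome-associated RNA was compared with total RNA in wild type to ask which RNAs ribosomes bind more or less. Replication-type histone genes were higher on polysomes: of the 13 genes, 11 were higher and 0 were lower (12 and 0 adjusted over the list alone, 12 and 0 after rescaling). Camera placed histone genes above other features (adjusted p = 7.81e-12, but 0.224 estimated). H4h stood at 487 ± 4.35 CPM on polysomes against 165 ± 1.51 CPM in total RNA (AT5G59970, log2 1.56 ± 0.17, adjusted p = 2.19e-04) and H3.1e at 269 ± 26.1 CPM against 110.4 ± 32.1 CPM (AT3G27360, log2 1.31 ± 0.22, adjusted p = 0.00389), with reads of identical copies hard to tell apart. MET1 RNA was 12.3 ± 2.83 CPM against 30.4 ± 0.556 CPM (log2 -1.30 ± 0.30, adjusted p = 0.0187, up to 0.137 without total replicate 1, total replicate 2 or polysome replicate 2) and DDM1 RNA 6.94 ± 1.86 CPM against 6.66 ± 2.35 CPM (log2 0.07 ± 0.76, adjusted p = 1). Of the 1983 transposon annotations, 1067 without a read in either fraction, 21 were higher and 63 lower (1 to 18 and 21 to 29 without 1 library), with a median log2 difference of 0, and they did not pass camera (adjusted p = 0.866). Over all features 2079 were called, 825 higher and 1254 lower, against 1124 and 1104 with median-of-ratios scaling. Leaving out total replicate 1, total replicate 2, polysome replicate 1 or polysome replicate 2 gave 621, 779, 691 and 809 calls, and 15 of the 47 calls of named features passed with each of them left out in turn.

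The features with the largest positive differences included AT1G45223 (93.1 ± 7.01 CPM against 5.76 ± 3.95 CPM, log2 4.06 ± 0.56, adjusted p = 0.00125), AT3G01185 (log2 3.77 ± 0.69, adjusted p = 0.00599, up to 0.0549 without polysome replicate 1) and AT2G38900, which had no read in total RNA and was at least 13.9-fold higher on polysomes (adjusted p = 0.00201). Those with the largest negative differences included AT5G48570 (13.1 ± 11.3 CPM against 414 ± 0.237 CPM, log2 -5.23 ± 0.55, adjusted p = 1.94e-04), the small nucleolar RNAs SNOR108 (AT5G41471, log2 -4.55 ± 0.52, adjusted p = 3.56e-04) and U3D (AT5G54075, log2 -4.32 ± 0.47, adjusted p = 2.67e-04), and AT1G56660 (log2 -4.48 ± 0.63, adjusted p = 0.00129). Among transposon annotations AT2TE84980 (log2 -4.46 ± 0.56, adjusted p = 6.76e-04) was lower and AT1TE56805 (log2 3.77 ± 0.58, adjusted p = 0.00217) higher. EVD had 0.0469 ± 0.0663 CPM on polysomes and 1.21 ± 1.71 CPM in total RNA, CAC1 and VANDAL21 had no read in either, and 0 of these 3 were called by limma (0 at an unadjusted p, 0 by edgeR and 0 by DESeq2, and 0 adjusted over the list alone). Of the 13 stress genes, 0 were higher and 3 were lower (0 and 3 adjusted over the list alone). Stress genes did not pass camera (adjusted p = 0.0555). The lower genes were HSP101 (log2 -3.98 ± 0.63, adjusted p = 0.00266), HSP90.1 (log2 -3.64 ± 0.50, adjusted p = 0.00124) and HSFA2 (log2 -2.13 ± 0.51, adjusted p = 0.0232, up to 0.135 without total replicate 1, total replicate 2 or polysome replicate 2), and the median of the heat-shock genes was 123 and 36.7 CPM in the polysome libraries.

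Of the 35 silencing genes, 0 were higher and 7 were lower on polysomes (0 and 9 adjusted over the list alone), DCL2 (AT3G03300, a Dicer-like gene, log2 -2.45 ± 0.61, adjusted p = 0.0257, up to 0.220 without total replicate 1, total replicate 2 or polysome replicate 1) among them. Camera placed silencing genes below other features (adjusted p = 3.09e-05, but 0.224 estimated). Of the 18 ribosomal protein genes, 4 were higher and 0 were lower (4 and 0 adjusted over the list alone), RPL10A (AT1G14320, log2 0.73 ± 0.17, adjusted p = 0.0193, up to 0.136 whichever library was left out) among them. Camera placed this list above other features (adjusted p = 0.00910, but 0.632 estimated). Of the 9 translation factor genes, 1 was higher and 1 was lower (2 and 2 adjusted over the list alone, 2 and 1 after rescaling): PAB2 (AT4G34110, a poly(A)-binding protein gene, log2 -1.71 ± 0.21, adjusted p = 5.15e-04) was lower and EF1A-A4 (AT5G60390, log2 0.78 ± 0.17, adjusted p = 0.0159, up to 0.149 whichever library was left out) higher. This list did not pass camera (adjusted p = 0.629). Of the 20 genes with a conserved upstream open reading frame, 0 were higher and 3 were lower (0 and 3 adjusted over the list alone), BZIP53 (log2 -1.60 ± 0.19, adjusted p = 4.21e-04) among them. Camera placed this list below other features (adjusted p = 0.0263, but 0.569 estimated). Of the 6 noncoding RNAs, 0 were higher and 1 was lower (0 and 3 adjusted over the list alone), TAS2 (log2 -1.83 ± 0.35, adjusted p = 0.00784, up to 0.0589 without total replicate 1, total replicate 2 or polysome replicate 2). Camera placed these noncoding RNAs below other features (adjusted p = 0.0335, but 0.251 estimated). Of the 13 photosynthesis genes, 3 were higher and 0 were lower (5 and 0 adjusted over the list alone), RBCS2B (AT5G38420, log2 0.82 ± 0.18, adjusted p = 0.0159, up to 0.117 whichever library was left out) among them. Photosynthesis genes did not pass camera (adjusted p = 0.0555, upward of the others, with median log2 -0.02 and mean log2 0.23). Of the 9 tapetum markers, 0 were higher and 2 were lower (0 and 3 adjusted over the list alone), GRP17 (log2 -2.88 ± 0.59, adjusted p = 0.0113, up to 0.0728 whichever library was left out) among them. Camera placed tapetum markers below other features (adjusted p = 0.0335, but 0.632 estimated). Of the 19 floral and meristem regulators, 1 was higher and 0 were lower (1 and 0 adjusted over the list alone), FT (log2 2.44 ± 0.53, adjusted p = 0.0143, up to 0.144 whichever library was left out). This list did not pass camera (adjusted p = 0.102).

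The same comparison in ddm1 asked whether transposon RNAs that accumulate in the mutant are bound by ribosomes. The 1089 transposon annotations that rose in ddm1 total RNA were lower on polysomes than in total RNA, with a median log2 difference of -1.74 (interquartile range -2.41 to -0.96, and median -1.73 at the 3-read floor), and 94.1% of them lay below 0. Limma called 451 of them lower and 0 higher, and the median of 20151 genes was 0.09. With the elements chosen anew, 260 of 884, 250 of 905, 152 of 1034 and 166 of 1035 were lower without total replicate 1, total replicate 2, polysome replicate 1 or polysome replicate 2 of ddm1, and 281 of 1111 at a pseudocount of 0.1. Set against the genes, camera gave p = 6.82e-54, and p = 2.63e-05 with estimated correlation. In 10000 lists of genes drawn to match the elements in ddm1 total RNA level, the medians ran from -0.01 to 0.17, and 0 lay at or below that of the elements. Over all 1983 transposon annotations tested, 474 were lower and 6 higher (median log2 -1.06, camera adjusted p = 1.38e-22, and 0.00781 estimated). AT1TE46765 stood at 2.45 ± 0.524 CPM on polysomes against 47.3 ± 11.3 CPM in total RNA (log2 -4.01 ± 0.49, adjusted p = 6.36e-04), and AT2TE19240 at 0.779 ± 0.631 CPM against 16.6 ± 2.09 CPM (log2 -3.83 ± 0.57, adjusted p = 0.00187). EVD was 33.7 ± 1.58 CPM on polysomes against 102 ± 33.8 CPM (log2 -1.55 ± 0.77, adjusted p = 0.253), VANDAL21 113 ± 9.76 CPM against 142 ± 1.16 CPM (log2 -0.33 ± 0.32, adjusted p = 0.591) and CAC1 0.249 ± 0.352 CPM against 0.471 ± 0.666 CPM (log2 -0.26 ± 0.65, adjusted p = 0.858), so limma called 0 of the 3 listed elements (0 at an unadjusted p, 0 by edgeR and 0 by DESeq2, and 0 adjusted over the list alone). In wild type, where 9 of the risen elements reached 5 CPM in total RNA, those 9 had a median log2 difference of -1.19. The labels do not say whether total and polysome RNA came from the same plants.

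**Figure D3:**
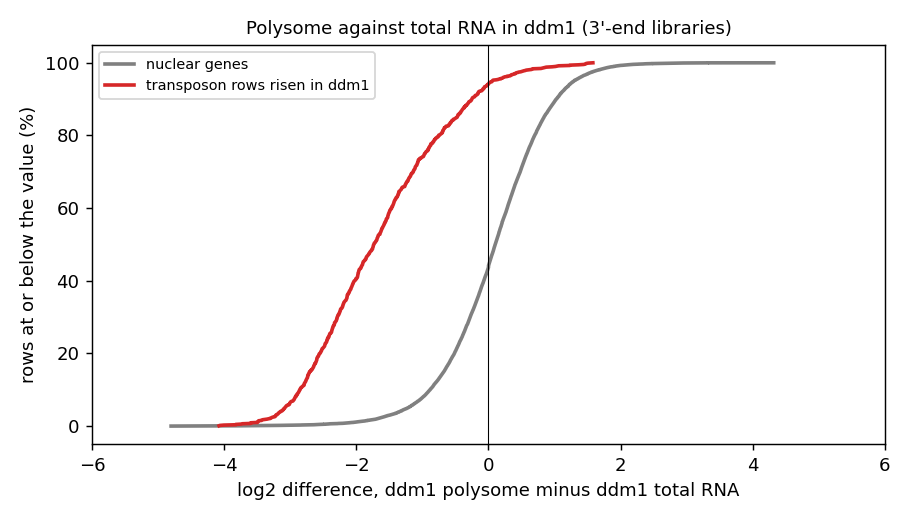
Share of features (percent, vertical axis) at or below each log2 difference between polysome and total RNA of ddm1 (horizontal axis), for nuclear genes in grey and for the 1089 transposon annotations that rose in ddm1 total RNA in red. The red curve crosses its midpoint at -1.74 and lies left of the grey curve.

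Over all features 1915 were called between polysome and total RNA of ddm1, 778 higher and 1137 lower. Leaving out total replicate 2, polysome replicate 1 or polysome replicate 2 gave 904, 449 and 472 calls, and 14 of the 39 calls of named features passed with each library left out in turn. MET1 RNA was 16.6 ± 4.52 CPM against 28.9 ± 0.875 CPM (log2 -0.80 ± 0.30, adjusted p = 0.123) and DDM1 RNA 0.743 ± 0.358 CPM against 1.11 ± 0.461 CPM (log2 -0.37 ± 0.76, adjusted p = 0.823). Small nucleolar RNAs had the largest negative differences among genes, with AT1G03746 (0.476 ± 0.501 CPM against 23.2 ± 2.02 CPM, log2 -4.70 ± 0.55, adjusted p = 4.93e-04) and AT2G20722 (log2 -4.69 ± 0.53, adjusted p = 4.77e-04), and AT2G35382, which had no read on polysomes, at least 31.2-fold lower (adjusted p = 2.15e-04). AT5G46160 (31.9 ± 8.24 CPM against 2.97 ± 0.876 CPM, log2 3.22 ± 0.47, adjusted p = 0.00159) had a large positive difference. QQS was lower on polysomes (log2 -2.42 ± 0.34, adjusted p = 0.00133), the 1 call among the 9 methylation-controlled genes (2 adjusted over the list alone). Methylation-controlled genes did not pass camera (adjusted p = 0.381, downward of the others, with median log2 0.02 and mean log2 -0.31). Of the 13 histone genes, 10 were higher and 0 were lower (11 and 0 adjusted over the list alone), H4h (log2 1.43 ± 0.17, adjusted p = 4.93e-04) among them. Camera placed histone genes above other features (adjusted p = 2.88e-10, but 0.143 estimated). Of the 9 tapetum markers, 3 were higher and 0 were lower (4 and 1 adjusted over the list alone). Camera placed tapetum markers above other features (adjusted p = 0.0101, but 0.492 estimated). A6 (AT4G14080, log2 1.71 ± 0.37, adjusted p = 0.0131, up to 0.171 without total replicate 2, polysome replicate 1 or polysome replicate 2) was one of them.

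Of the 35 silencing genes, 0 were higher and 2 were lower on ddm1 polysomes (0 and 2 adjusted over the list alone), AGO1 (AT1G48410, the main Argonaute of microRNAs, log2 -1.27 ± 0.23, adjusted p = 0.00518, up to 0.0828 without polysome replicate 1 or polysome replicate 2) among them. Camera placed silencing genes below other features (adjusted p = 0.0149, but 0.492 estimated). Of the 18 ribosomal protein genes, 2 were higher and 0 were lower (2 and 0 adjusted over the list alone), RPL24B (AT3G53020, log2 1.16 ± 0.20, adjusted p = 0.00419, up to 0.0673 without polysome replicate 1) among them. Camera placed ribosomal protein genes above other features (adjusted p = 0.00844, but 0.492 estimated). Of the 9 translation factor genes, 2 were higher and 1 was lower (2 and 2 adjusted over the list alone), PAB2 (log2 -1.80 ± 0.21, adjusted p = 4.79e-04) being the lower one. Translation factor genes did not pass camera (adjusted p = 0.654). Of the 6 noncoding RNAs, 0 were higher and 2 were lower (0 and 2 adjusted over the list alone), TAS2 (log2 -1.57 ± 0.35, adjusted p = 0.0163, up to 0.135 without total replicate 2, polysome replicate 1 or polysome replicate 2) among them. Camera placed these noncoding RNAs below other features (adjusted p = 0.0101, but 0.143 estimated). Of the 20 genes with a conserved upstream open reading frame, 0 were higher and 2 were lower (0 and 2 adjusted over the list alone). This list did not pass camera (adjusted p = 0.0902).

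Polysome-associated RNA of ddm1 was compared with that of wild type to ask which RNAs differ in the ribosome-bound pool. Of the transposon annotations, 746 were higher and 35 lower in ddm1, with a median log2 difference of 1.36 (1.29 at the 3-read floor). Camera placed them above the other features (adjusted p = 3.01e-36, and 0.00249 estimated). AT5TE42470 stood at 585 ± 85.5 CPM against 0.516 ± 0.729 CPM (log2 9.38 ± 0.38, adjusted p = 7.43e-09), and of the 3 listed elements 2 were higher and 0 were lower (2 and 0 adjusted over the list alone). AT1G59930 stood at 664 ± 42.8 CPM against 0.0938 ± 0.133 CPM (log2 10.14 ± 0.75, adjusted p = 1.53e-06) and AT5G34885 at 0.245 ± 0.346 CPM against 40.1 ± 1.52 CPM (log2 -5.85 ± 0.52, adjusted p = 9.40e-06). HSP17.6A was lower in ddm1 (log2 -6.48 ± 0.61, adjusted p = 1.39e-05), as were 8 of the 18 heat-shock genes. DDM1 RNA was 0.743 ± 0.358 CPM against 6.94 ± 1.86 CPM (log2 -2.59 ± 0.76, adjusted p = 0.0532, but 0.0268 by edgeR and 0.00742 by DESeq2, the cause was not tested) and MET1 RNA 16.6 ± 4.52 CPM against 12.3 ± 2.83 CPM (log2 0.42 ± 0.30, adjusted p = 0.524). Of the 6 pollen markers 0 were higher and 4 were lower (0 and 4 adjusted over the list alone). Camera placed pollen markers below other features (adjusted p = 5.80e-06, but 0.227 estimated), whereas limma called 0 of the 9 tapetum markers (2 at an unadjusted p, 1 by edgeR and 1 by DESeq2, and 1 adjusted over the list alone). Over all features 2004 were called, 1123 higher and 881 lower. Leaving out wild-type replicate 1, wild-type replicate 2, ddm1 replicate 1 or ddm1 replicate 2 gave 951, 1197, 971 and 927 calls, and 3129 were made with only the compared groups in the fit.

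Whether the polysome-to-total ratio differs between ddm1 and wild type was tested as an interaction. For most transposon annotations the test did not measure this: 1170 of the 1983 tested had no read in wild-type total RNA and 1067 none in either wild-type fraction. Their median interaction of log2 -0.90 therefore mostly repeats the polysome-to-total difference of ddm1 (median log2 -1.06), and the list test is not reported. Among the 218 with at least 5 CPM in wild-type total RNA, chosen after the result was seen, the median was log2 0.19 and 0 were called lower. That choice can raise the median, and the set holds only 9 of the 1089 risen elements. Limma called 43 features, 5 higher and 38 lower in ddm1. The 38 were all transposon annotations. Of them 30 had no read in wild-type total RNA, 15 none in either wild-type fraction and 0 reached 5 CPM in that total RNA, so no lower ratio than in wild type was shown. Among the 5 that were higher were AT5G48570 (log2 5.81 ± 0.78, adjusted p = 0.0259, up to 0.352), SGT1A (AT4G23570, log2 2.64 ± 0.43, adjusted p = 0.0432, up to 0.352) and ROF1 (AT3G25230, log2 2.35 ± 0.38, adjusted p = 0.0432, up to 0.352), lost without most libraries. In wild-type total RNA, where heat-shock RNAs were high, they stood at 415 and 414, 188 and 196, and 310 and 315 CPM, against 2.67 and 1.44, 12.6 and 17.5, and 52.1 and 40.5 CPM in that of ddm1. MET1 (log2 0.49 ± 0.42, adjusted p = 0.858) and DDM1 (log2 -0.45 ± 1.07, adjusted p = 0.968) were not called. The calls rest on single libraries: without total wild-type replicate 1, total wild-type replicate 2, either total ddm1 library or either polysome ddm1 library 0 were made, without polysome wild-type replicate 2 11, and without polysome wild-type replicate 1 56. The unadjusted p was under 0.05 for 1723 features, edgeR called 1, higher, and DESeq2 28, 25 higher and 3 lower, 0 of them transposon annotations. Median-of-ratios scaling moved the median of all features from log2 0.10 to -0.04. Of the 9 tapetum markers limma called 0 (7 at an unadjusted p, 0 by edgeR and 1 by DESeq2, and 4 adjusted over the list alone, median log2 1.65). Camera placed tapetum markers above other features (adjusted p = 3.74e-08, but 0.233 estimated). Of the 13 stress genes limma called 0 as well (4 at an unadjusted p, 0 by edgeR and 0 by DESeq2, and 3 adjusted over the list alone). Camera placed stress genes above other features (adjusted p = 0.00199, but 0.611 estimated). These genes include heat-shock genes, which were high in the wild-type libraries.

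The small RNA library of met1 was described by the sizes of its reads, since plants make 21-nt RNAs mostly from microRNA precursors and 24-nt RNAs from silenced repeats. It held 3905777 distinct sequences of 15 to 50 nt, and shares are given of all reads. Reads of 21 nt made up 29.8%, of 22 nt 9.77%, of 23 nt 6.61% and of 24 nt 13.4%, or 0.451 reads of 24 nt per read of 21 nt. Counted by distinct sequence the shares of 21 nt and 24 nt were 10.1% and 18.4%. Of 21-nt reads 60.1% began with U, and of 24-nt reads 45.0% began with A. The most frequent sequence was that of miR166, a microRNA that targets leaf polarity genes, with 7.44% of all reads, followed by miR165 with 4.91%. The 11 listed 21-nt microRNAs, mainly miR166 and miR165, made up 41.9% of 21-nt reads. The other listed sequences ran from 0 reads for miR845a, which targets retrotransposons (upper 95% limit 4.48e-06%), and 32 for miR172a to 48390 for miR168a. With no second small RNA library, nothing was tested, and counting limits do not cover differences between plants.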

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

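All tests in this part that weigh an explanation were chosen after the result was seen. The interaction of genotype and fraction was called for 43 features, and 9110 features differed between met1 and ddm1 in total RNA-seq, both flagged as differences between groups. Of the 43, 38 were transposon annotations below 5 CPM in wild-type total RNA, 30 of them without a read there, so for these a ratio lower than in wild type was not measured. The count of 43 is 0 without either library of total wild-type, total ddm1 or polysome ddm1 RNA, 56 without polysome wild-type replicate 1 and 11 without polysome wild-type replicate 2, and the count of 9110 is 5269 without ddm1 replicate 1, 5709 without ddm1 replicate 2 and 4852 without met1 replicate 1.

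Transposon RNAs that rose in ddm1 were low on ddm1 polysomes, with a median log2 difference of -1.74 to total RNA over 1089 elements. Counts near the floor are argued against, since the 400 elements with at least 20 CPM had a median of -2.30 (interquartile range -2.70 to -1.48, and -2.35 to -2.22 over the 4 pairs of libraries). Choosing elements on the same total RNA libraries is argued against, since the 1086 elements chosen in total RNA-seq had a median of -1.56. Different plant material in the total and polysome libraries cannot be told apart from a difference in ribosome binding, because the labels do not say whether fractions share plants, and 3 of 9 tapetum markers were higher on ddm1 polysomes. A candidate explanation, untested by other data, is that these RNAs are bound by ribosomes less than gene RNAs are.

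Heat-shock RNAs were high in the wild-type 3-prime-end libraries, at a median of 200.2 CPM against 11.7 CPM in ddm1 and 13.8 CPM in met1. Genotype alone is argued against, since the 13 heat-shock genes tested in total RNA-seq had a median log2 difference of 0.0217 between the mutants and wild type. The pattern is a difference between genotypes within the 3-prime-end assay, so a method effect alike in all genotypes would not give it. That the mutant libraries held 0.0636 of the wild-type level restates the pattern and is no separate test. Handling or growth of the wild-type tissue cannot be told apart from a joint effect of genotype and method, because these libraries are also all the wild-type ones of the assay, and the 2 wild-type polysome libraries differed 3.36-fold. A genotype effect that needs conditions met only by the plants of this assay stays open and untested, and this pattern bears on the comparisons with wild type in that assay.

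CAC1 and ROS1 levels in ddm1 differed between the assays: CAC1 was 1250.2 CPM and 1459.5 CPM in total RNA-seq but 0.941 CPM and 0 CPM in 3-prime-end RNA, and the log2 difference of ROS1 to wild type was -0.86 and -4.65. A failure of 3-prime-end reads to cover CAC1 is argued against, since its mean in met1 libraries of that assay was 39.2 CPM. Exchanged ddm1 and met1 labels in one table are argued against, since the met1 against ddm1 differences of 1280 transposon annotations correlated at 0.576 between tables, over features that are not independent replicates. Different ddm1 plants in the tables cannot be told apart from effects of the assay, because each table has its own libraries, and 6.23% of the 2454 features called in ddm1 in both, 153, went opposite ways, 18 of them by at least 2-fold in both. No biological explanation was tested.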

How the results depend on the processing

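Nuclear features only, elements chosen in total RNA-seq and calls shared with total RNA-seq were chosen after the result was seen. Counts of all calls, or of transposon annotations higher and lower, that stayed within 1.5 times the reported count are not listed. A fold of at least 2 gave 4378 calls of 15570 for ddm1, 2732 of 10539 for met1 and 1971 of 9110 for met1 against ddm1 in total RNA-seq, by its construction. A fit with only the compared groups, which has fewer libraries, gave 1073 calls for met1 in 3-prime-end RNA (1969), 3316 for polysome against total RNA in wild type (2079), 3129 for ddm1 on polysomes (2004) and 0 for the interaction (43). Without a trend of the variance, polysome against total RNA gave 988 calls in wild type and 1204 in ddm1 (1915), and the interaction 144. Also called in total RNA-seq were 1052 features of met1 in 3-prime-end RNA. The interaction gave 0 calls at a pseudocount of 0.1 and 141 at 1, 7 with no filter, 1 with edgeR (1063 at an unadjusted p), 28 with DESeq2, 5 without transposon annotations below 5 CPM in wild-type total RNA and 60 after median-of-ratios scaling, against 1723 at an unadjusted p with limma. The cause was not tested.

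With replicate number as a block the interaction gave 0 calls. Of the 55 list tests that passed camera, 8 passed with estimated correlation, all of transposon annotations and 1 of them the interaction left out of the report, 37 with fry and 52 after median-of-ratios scaling. The cause was not tested. Transposon annotations higher and lower in total RNA-seq were 3275 and 567 for ddm1, 2569 and 381 for met1 and 565 and 1753 for met1 against ddm1 with no filter, and 988 and 81, 942 and 58 and 138 and 608 with a filter of 5 CPM, by construction. With edgeR and DESeq2, 109 and 94 were lower in ddm1, 97 and 84 lower in met1 and 180 and 162 higher in met1 than in ddm1. A fold of at least 2 left 61, 36 and 102 of the limma calls of these 3 kinds. In 3-prime-end RNA, lower in ddm1 were 32 with a filter of 5 CPM, 36 with only the compared groups, 38 with edgeR and 15 also in total RNA-seq. Lower in met1 were 57 with no filter, and 12, 7, 14 and 6 with those settings, and 19 with DESeq2. On polysomes 38 were higher in wild type with only the compared groups and 13 without a trend, in ddm1 10 higher and 303 lower at a pseudocount of 0.1 and 15 higher with no filter, and 62 and 7 lower in ddm1 than in wild type with only the compared groups and also in total RNA-seq. The cause was not tested. The share of 24-nt reads was 13.44%, 18.37% of distinct sequences and 13.42% of reads of sequences with at least 2 reads.

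Leaving out each library in turn, with a lone library assumed to vary like the other groups, gave 12962 to 13502 calls for ddm1, 6845 to 7962 for met1 and 4852 to 6592 for met1 against ddm1 in total RNA-seq. In 3-prime-end RNA it gave 1937 to 2869 for ddm1, 1214 to 2349 for met1, 621 to 809 and 449 to 1294 for polysome against total RNA in wild type and ddm1, 927 to 1197 for ddm1 on polysomes and 0 to 56 for the interaction, with the libraries given in the report. Transposon annotations called higher and lower were 1330 to 1673 and 125 to 186 for ddm1 and 1449 to 1472 and 71 to 111 for met1 in total RNA-seq. In 3-prime-end RNA they were 865 to 905 and 18 to 51 for ddm1, 605 to 767 and 4 to 36 for met1, 0 to 14 and 158 to 269 for polysome against total RNA in ddm1 and 505 to 523 and 11 to 15 for ddm1 on polysomes. The median of the risen transposon annotations on ddm1 polysomes was -1.92 to -1.77 without 1 library, -1.98 for elements with log2 of at least 2 and 5 CPM, -1.56 for elements chosen in total RNA-seq and -1.82 with nuclear features only, below 0 and past camera in each, as at both other pseudocounts.

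For the 308 named results, 4918 values were recomputed: 4416 kept direction and side of the threshold, 481 lost their call, 7 gained one and 14 changed sign. In ddm1 total RNA-seq, RPL3A was log2 -0.0894 with quantile normalization, EF1A-A3 7.70e-04 with DESeq2, and H4a 0.0381 with median-of-ratios scaling, 0.0307 with edgeR and 0.0455 with DESeq2. In 3-prime-end RNA, MET1 in ddm1 was 0.0567 with median-of-ratios scaling, 0.0469 with edgeR and 0.0571 with DESeq2. DDM1 in met1 was 0.0259 with edgeR, 0.0415 with DESeq2, and -1.70 to 0.99 without each library in turn, with 0.99 without met1 replicate 1. DDM1 on wild-type polysomes was -0.27 to 0.41 without each library in turn, with -0.27 without total replicate 2 and -0.19 without polysome replicate 2, and -0.0194 with nuclear features only. None of the MET1 and DDM1 values among these was called, and the cause was not tested. On simulated data 5.97% of 2-fold changes were recovered in 3-prime-end total RNA and 100% in total RNA-seq, which differ in depth and in the spread between replicates. Family means, transposon classes and small RNA positions, absent from the files, were not run.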

Other observations

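The classes in this paragraph were chosen after the data were seen. Organelle and small nucleolar RNAs were lower on polysomes than in total RNA. In wild type 74 of 112 chloroplast features tested were lower (median log2 -2.14, camera adjusted p = 0.0109 with estimated correlation), 40 of 73 mitochondrial features (-2.31, 0.00105) and 30 of 57 small nucleolar RNAs (-2.39, 4.64e-04). In ddm1 the values were 75 (-2.02, 0.0102), 33 (-1.96, 0.00109) and 35 (-2.74, 1.95e-04). The 18S rRNA took 1.05% of reads in total RNA-seq replicate 1 of ddm1 and 0.0962% to 0.171% in the other 5 libraries of that assay.

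Differences to wild type correlated between ddm1 and met1 at 0.910 in total RNA-seq and 0.789 in 3-prime-end RNA. Shared controls alone gave means of 0.498 and 0.476 in 20 simulations without an effect, with covariances of 0.0154 and 0.155 against 1.77 and 1.60 observed. In total RNA-seq 2398 features rose in both mutants (436 if the calls were independent), 6746 fell in both (4106) and 122 went opposite ways, against 4080 (1394), 3274 (1053) and 109 with median-of-ratios scaling, chosen after the data were seen. In 3-prime-end RNA the counts were 931 (96.8), 400 (45.4) and 6. The controls were not split, so these counts above independence include what shared controls add.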
